A study of Mus musculus with 2 samples.

How the data were processed

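Polyadenylated RNA was measured by single-end RNA sequencing in CH12.LX, an immortalized mouse B cell lymphoma line, in 2 libraries that the labels give as biological replicates 1 and 2 of separate biosamples. The labels hold no second condition, so both libraries form 1 group and no comparison between conditions exists. Per the labels, the strain is B10.H-2aH-4bp/Wts and the sex is female.

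Per the file headers and the deposited notes, each library has a table of genes and a table of transcripts made from its transcriptome alignments, on the mm10 assembly with the GENCODE M4 annotation. The aligner, the quantification tool and their versions are not given in the sources used here. The deposited expected counts are estimated read counts per gene or transcript that need not be whole, because reads matching several genes are split between them. The deposited TPM and FPKM values are both corrected for gene length and scaled by the authors to the depth of each library. The deposited posterior mean counts, their standard deviations and the posterior mean TPM values are per the file headers a second estimate of the same quantities with its uncertainty. The deposited isoform values are the percent of a gene's expression on each transcript, per the file headers. The TPM scale is shared by all entries of a library, so a gain by very abundant transcripts lowers all others.

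Gene names, types and coordinates were taken from GENCODE M21 on GRCm38, the same assembly as mm10, by Ensembl identifier without its version. Of 43346 Ensembl entries, 42462 (98.0%) matched and 884 did not. A further 26248 entries carry only a number as identifier and name no gene. They held 0.0426% of the counts in replicate 1 and 0.0539% in replicate 2, but 18255 and 22456 TPM, and they stayed out of library sizes and tests. The 97 spike-in entries held 0 counts.

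Replicate 1 held 22996547 expected counts and replicate 2 held 25715408. A gene was called detected at 1 TPM or more in both replicates. Levels are given as mean ± SD over n = 2, and a share of counts in 1 library has a Wilson 95% interval. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules. A count of 0 was bounded with 3 counts.

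Expected counts were rounded to whole numbers for tests. Each of 15340 genes with at least 10 counts summed over both libraries was tested with a two-sided exact binomial test of its 2 counts against the TMM effective library sizes of edgeR 4.0.16, with Benjamini-Hochberg adjustment at 0.05. That test compares the 2 libraries and not conditions, and it holds counting error only. The biological coefficient of variation was the square root of edgeR's common dispersion. A log2 ratio of replicate 2 over replicate 1 used counts scaled to the mean library with a pseudocount of 0.5. Fixed gene lists were described by the percentile of their median among 10000 random lists of the same size. For levels the random lists came from all protein-coding genes, and for the difference between libraries they were matched on mean expression in 20 bins. Read assignment was called uncertain where the posterior SD exceeded 5% of the posterior mean count in a library. It was called certain otherwise, which does not rule out reads moved between near copies. For selected genes, the share of 36-mers of the annotated transcripts that occur in no other gene was counted.

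Before the data were examined, 27 gene lists with 378 distinct symbols were fixed, of which 373 were measured. Iglc1, Iglc3, Iglc4, H2-Ea and H2-L were not analysed here. The genes named were fixed by the same rule in advance. They are the 20 protein-coding genes with the highest mean TPM, up to 4 of the highest members per list with those needed to say what was not detected, and members of the B cell identity, constant region, MHC class II and sex-linked lists. The rule adds the 5 largest ratios in each direction among genes past the exact binomial test with a mean of at least 100 counts, the 3 leading heavy chain and the 3 leading light chain V genes, and the leading transcript of the isoform genes. A few list members are not reported here by name. Cd5, Myc and Atf4 are further list members named after their values were seen, and other genes outside the rule are said to be so where they appear.

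The tests were tested on simulated data made from the means and depths of these libraries. For the binomial test and the random lists, the simulated counts of each gene were independent and held counting error only. A low rate of false calls was thus built in, and these rates do not carry over to the measured libraries. For replicate 2 against replicate 1 with 15340 genes, the binomial test called 70 of 100 genes changed by 1.5-fold, 75 of 100 genes changed by 2-fold and 6 of 15140 unchanged genes. A simulated coefficient of variation of 10% was recovered as 10.0%. Of 200 random lists, 12 lay outside the central 95% of matched lists. Alternatives covered detection thresholds, units, size factors of DESeq2 1.42.0, library totals, count filters, a negative binomial exact test, pseudocounts and each replicate left out. Posterior mean counts, a limit on read assignment uncertainty and the removal of mitochondrial and rRNA-repeat genes were added after seeing the data. R 4.3.3, Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used.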

Results

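Polyadenylated RNA of CH12.LX, a mouse B cell lymphoma line, was sequenced in 2 biological replicates with 22996547 and 25715408 expected counts. The labels name no treatment or second line, so the values describe the transcriptome of this line and the difference between its 2 libraries. The counts of the 2 libraries differed by more than counting noise, with a chi-square of 33.2 per degree of freedom over 15340 genes and 23.4 over the 12711 with certain read assignment. That value alone does not tell separate cultures from repeat runs of 1 sample, and the labels give separate biosamples.

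CH12.LX expressed 11880 genes at 1 TPM or more in both replicates, of which 10317 were protein coding. By the mean of the replicates the leading protein-coding gene was the mitochondrial mt-Atp8 (12634 ± 5350 TPM, SD, n = 2), followed by the elongation factor Eef1a1 (9234 ± 160), mt-Co1 (7398 ± 2943), the chaperone Hspa8 (5801 ± 141) and Cd74, the invariant chain of MHC class II (5621 ± 86.1). In replicate 1 alone Eef1a1 (9347 TPM) stood above mt-Atp8 (8851), and mt-Co1 (5317) below Hspa8 (5901), Cd74 (5682) and Npm1 (5463). The order covers genes annotated as protein coding only, a type that leaves out immunoglobulin genes. Of those, Igkc averaged 7838 TPM, above mt-Co1, and Igkv10-96 and Igha averaged 4863 and 3941. The pseudogenes Gm10925 (10405 and 17981 TPM in replicates 1 and 2) and Gm28661 (10413 and 17024) stood above mt-Atp8. All of their 36-mers occur in mitochondrial genes, so the order may depend on how shared reads were split. The pseudogene Ftl2-ps averaged 3721 TPM against 36.1 for the protein-coding Ftl1, whose posterior SD was 7.82% and 7.11% of the count. Whether reads of Ftl1 were placed on Ftl2-ps was not tested, so the place of Ftl1 in the order is uncertain. These pseudogenes and Ftl1 were named after their values were seen. The chemokine Ccl22 was also among the 20 highest, at 3228 ± 164 TPM (SD, n = 2) on chromosome 8 from 94745590 to 94751699. The others were the ribosomal genes Rpl41, Rplp1, Rplp0, Rpl4, Rpl23, Rpl13a, Rpl26 and Rack1, the mitochondrial genes mt-Nd1 and mt-Cytb, and Npm1, Ppia, Ptma and Hsp90ab1. Of the 13138 genes at 1 TPM in either replicate, 90.4% were at 1 TPM in both, and this share was 97.0% for protein-coding genes.

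Genes of B cell identity were expressed nearly throughout, while those of other blood lineages and tissues were mostly at or near 0. Of 24 B cell identity genes, 23 were detected, and their median of 125 TPM lay at percentile 100 of random protein-coding lists. The highest were Cd24a (1474 ± 119 TPM, SD, n = 2), the B cell receptor component Cd79b (535 ± 14.4), Cd37 (316 ± 11.3) and the receptor component Cd79a (288 ± 36.6). Ms4a1, which encodes CD20, stood at 276 ± 12.2 TPM, and the transcription factors Ebf1 and Pax5 at 42.6 ± 2.89 and 31.9 ± 6.22. Above 100 TPM on average also lay Blnk (205), Spib (202), Pou2af1 (193), Tnfrsf13c (173), Tcf3 (163), Cd22 (138), Cd40 (112) and Ralgps2 (102). Lower on average were Cd72 (53.7), Btk (46.2), Blk (42.6), Bcl11a (41.5), Bank1 (21.7), Fcrla (12.4) and Fcer2a (10.5). The complement receptor Cr2 was the gene missed, at 0.91 and 2.21 TPM in replicates 1 and 2.

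All 10 genes of the B-1 and CD5 B cell list were detected, led by Plscr1 at 156 and 144 TPM in replicates 1 and 2, Zbtb32 at 133 and 132, and Bhlhe41 at 87.7 and 82.7. Cd5 itself stood at 32.8 and 34.9 TPM. Of 10 germinal centre genes, 7 were detected. Rgs13 stood at 479 and 514 TPM, and Mef2b at 101 and 124, whereas Bcl6 reached 0.56 and 0.44 TPM and Bach2 and Gcsam were also not detected. Of 12 plasma cell genes, 11 were detected, with Mzb1 at 810 and 694 TPM, Jchain at 284 and 250, Tnfrsf13b at 231 and 260 and Xbp1 at 83.4 and 96.4, and Tnfrsf17 was the gene not detected. Only 2 of 13 pro-B and pre-B cell genes passed 1 TPM in both replicates, Vpreb3 at 80.7 and 99.4 TPM and Flt3 at 1.54 and 1.67. The recombinase genes Rag1 and Rag2 had 0 counts in both libraries, which allows up to 0.0132 and 0.0333 TPM at 3 counts over both.

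Of 16 T cell genes, 6 were detected, among them the kinase Lck at 136 and 100 TPM and Cd2 at 25.61 and 25.74. The CD3 chains Cd3g at 1.69 and 2.11 TPM and Cd3d at 1.14 and 1.63 were also detected, while Cd3e, Zap70, Themis and Bcl11b were not. None of 9 NK cell genes was detected, and Prf1 was the highest at 0.33 and 0.35 TPM. Of 16 myeloid genes, 3 were detected, Cd68 at 182 and 253 TPM, Itgam at 1.79 and 1.24 and Adgre1 at 1.64 and 1.34. Of 16 erythroid and megakaryocyte genes, 4 were detected, the globins Hba-a2 at 10.6 and 7.64 TPM, Hbb-bt at 5.52 and 5.05 and Hba-a1 at 2.44 and 3.42, and Itga2b at 1.77 and 2.65. The globin genes share reads with near copies, with a posterior SD of 8.44% to 29.9% of the count over Hba-a1, Hba-a2 and Hbb-bt, so the value of each is uncertain. Of 13 stromal and endothelial genes, 3 were detected, Pecam1 at 14.7 and 14.1 TPM, Tagln at 1.72 and 2.37 and Cdh5 at 1.1 and 1.0. Of 8 epithelial and hepatocyte genes, Epcam alone was detected, at 1.22 and 1.21 TPM. At 5 TPM in place of 1 TPM, 4 germinal centre, 1 pro-B and pre-B, 2 T cell, 1 myeloid, 2 erythroid and megakaryocyte, 1 stromal and endothelial and 0 epithelial and hepatocyte genes were detected, each a change of over 1.5 times. The myeloid count was 5 at 0.5 TPM and 1 at 1 FPKM, and the epithelial and hepatocyte count was 0 at 1 FPKM.

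**Figure D1:**
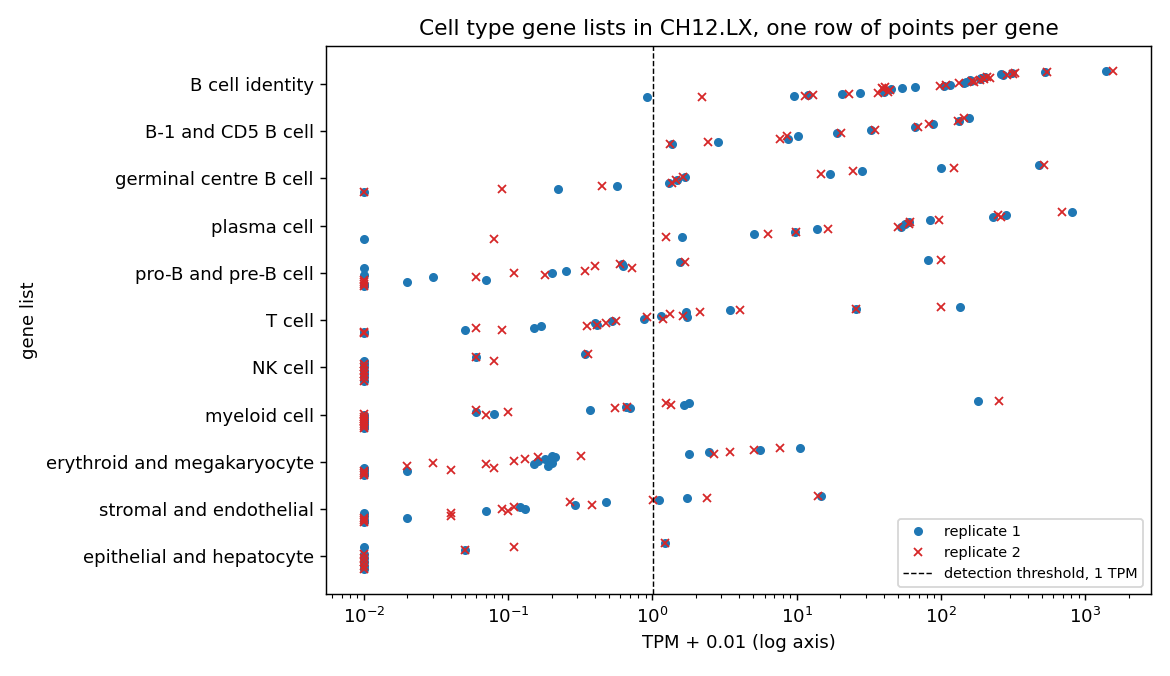
TPM of each gene of the cell type lists on a log axis, with replicate 1 as circles, replicate 2 as crosses and the detection threshold of 1 TPM as a dashed line. Of 24 B cell identity genes 23 lie right of the line in both replicates, against 0 of 9 NK cell genes.

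The immunoglobulin transcripts were dominated by 1 heavy chain constant region, 1 light chain constant region and 1 V gene for each. Igha, the constant region of IgA, stood at 3941 ± 99.9 TPM (SD, n = 2) and Ighm, that of IgM, at 1184 ± 109. Igha thus held 76.2% ± 1.22 of heavy chain constant region TPM and Ighm 22.8% ± 1.16 (SD, n = 2). As shares of counts, the Wilson 95% interval of Igha was 76.4% to 76.8% in replicate 1 and 75.3% to 75.8% in replicate 2. Ighg3 reached 40.4 ± 4.13 TPM, and Ighg2b, Ighe, Ighg1 and Ighg2c lay between 1.6 and 3.67 TPM on average. Ighd averaged 0.795 TPM. Of the 10 measured constant region genes, 9 were detected, and 5 at the higher threshold of 5 TPM. The kappa constant region Igkc stood at 7838 ± 671 TPM and the lambda constant region Iglc2 at 706 ± 127. Igkc thus held 91.8% ± 0.713 of the TPM of Igkc and Iglc2 together (SD, n = 2), the only listed light chain constant regions matched by name. Any lambda constant region without a matched name would be missing from this share. Igha lies on chromosome 12 from 113254830 to 113260236 and Ighm from 113418558 to 113422730, Igkc on chromosome 6 from 70726435 to 70726966, and Iglc2 on chromosome 16 from 19198396 to 19200351, on mm10.

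Of 173 heavy chain V genes, Ighv1-53 held 98.5% of their TPM in replicate 1 and 99.0% in replicate 2, at 2489 ± 428 TPM (SD, n = 2). Ighv1-55 and Ighv8-6 followed at 15.9 ± 0.863 and 2.42 ± 1.39 TPM. Of 103 kappa V genes, Igkv10-96 held 99.4% and 99.5%, at 4863 ± 209 TPM, with Igkv14-111 at 9.24 ± 0.0919. Igkv10-94, named after its value was seen, stood at 7.97 ± 1.87 with a posterior SD of 17.7% and 18.1% of the count, and is uncertain. The 3 lambda V genes summed to 12.37 and 11.99 TPM, with Iglv3 at 12.17 and 11.11. V genes resemble each other, and 31.7% of the 36-mers of Ighv1-53 and 56.2% of those of Igkv10-96 occurred in no other gene.

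**Figure D2:**
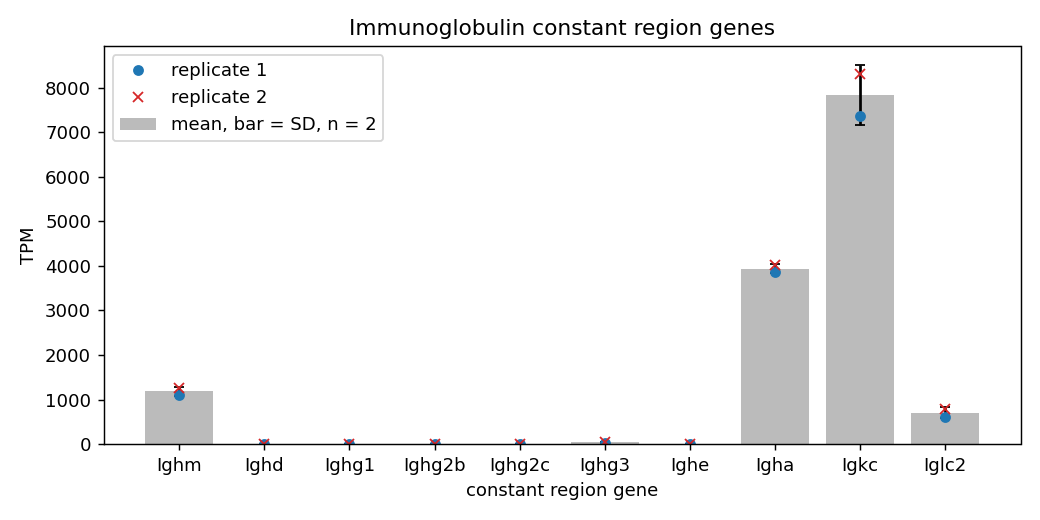
TPM of the constant region genes, with bars for the mean, error bars for the SD over n = 2, circles for replicate 1 and crosses for replicate 2. Igha at 3941 TPM exceeds Ighm at 1184 TPM, and Igkc at 7838 TPM exceeds Iglc2 at 706 TPM.

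All 12 measured MHC class II genes were detected, and so were all 15 of class I. Beside Cd74, the class II genes were led by H2-Ea-ps (781 and 788 TPM in replicates 1 and 2), H2-Aa (724 and 707), H2-Eb1 (622 and 604) and H2-Ab1 (406 and 483). H2-Ea-ps is annotated as a polymorphic pseudogene in the reference. Whether its transcript is functional in the strain of this line, whose label names H-2a, was not tested. The peptide-loading genes H2-DMb2, H2-DMb1 and H2-DMa averaged 135, 88.8 and 65.5 TPM, the transactivator Ciita 43.4, H2-Oa 26.6, H2-Ob 14.6 and H2-Eb2 10.7. Class I was led by B2m (1730 and 1412 TPM), H2-K1 (995 and 915), H2-D1 (741 and 646) and Psmb8 (444 and 458).

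All 25 class switch and end joining genes were detected, led by Apex1 (281 and 267 TPM) and Parp1 (267 and 229). Of 20 cell cycle genes, 19 were detected, led by Pcna (430 and 405 TPM) and Top2a (328 and 328), and Ccnd1 was not, at 0.12 and 0.11 TPM. All 16 cholesterol synthesis genes were detected, led by Srebf2 (119 and 137 TPM), and all 15 glycolysis genes, led by Gapdh (1742 and 1935) and Eno1 (1456 and 1368). All 16 TLR and NF-kB genes were detected, led by Ly86 (285 and 243 TPM) and Nfkb1 (208 and 247). All 12 reference genes and all 16 genes of the isoform list were detected.

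Response and survival genes were more uneven. Of 20 apoptosis genes and oncogenes, 16 were detected, with Trp53 at 240 and 274 TPM, Bcl2a1b at 270 and 206 and Myc at 131 and 131. Mycl stood at 0.5 and 0.33 TPM, and Mycn and the cell cycle inhibitors Cdkn2a and Cdkn2b had 0 counts in both libraries, which allows up to 0.104 TPM of Cdkn2a and 0.0641 TPM of Cdkn2b at 3 counts over both. Cdkn2a (chromosome 4 from 89274471 to 89294653) lies in a run of 9 gene entries without a read. The nearest entries at 1 TPM or more on either side were Klhl9 (12.5 and 14.0 TPM) and Gm12609 (24.5 and 21.1). The 41 entries between them held at most 6.79 counts in a library, so low values extend beyond the run. Mtap in that run, Klhl9 and Gm12609 were named after their values were seen. Of 15 immediate early and heat shock genes, 10 were detected, and Fos reached 0.2 and 0.08 TPM beside Hspa8 and Hsph1 (88.7 and 84.0). Of 13 interferon-stimulated genes, 8 were detected, among them Bst2 (181 and 160 TPM) and Gbp2 (33.0 and 26.8), and 4 at 5 TPM. Of 10 hypoxia genes, 7 were detected, led by P4ha1 (30.9 and 28.2 TPM), and Car9 had 0 counts. Of 15 stress response genes, 13 were detected, led by Hsp90b1 (880 and 853 TPM), Hspa5 (639 and 581) and Phgdh (520 and 400), whereas Asns had 1 and 2 counts and Slc7a11 reached 0.17 and 0.27 TPM.

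**Figure D3:**
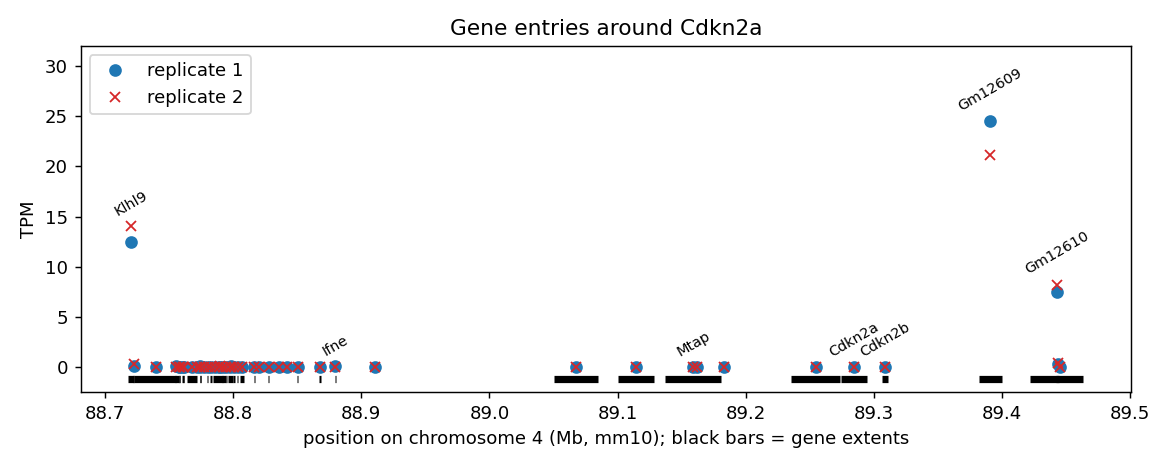
TPM of each gene entry against its position on chromosome 4 in Mb on mm10, with circles for replicate 1, crosses for replicate 2 and black bars for gene extents. Mtap, Cdkn2a and Cdkn2b lie at 0 between Klhl9 at 12.5 and 14.0 TPM and Gm12609 at 24.5 and 21.1 TPM.

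The Y-linked genes were expressed and Xist was not, in a line whose label gives the sex as female. Eif2s3y stood at 57.1 ± 9.29 TPM (SD, n = 2), Ddx3y at 27.2 ± 2.60, Kdm5d at 11.7 ± 0.0354 and Uty at 6.01 ± 0.827. Xist, the transcript that silences an X chromosome, had 1 and 0 counts, and its antisense Tsix 0 and 1. The X-linked Ddx3x stood at 271 ± 34.1 TPM, Kdm5c at 36.1 ± 3.37 and Kdm6a at 10.8 ± 1.41. Of 9 sex-linked genes, 7 were detected.

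**Figure D4:**
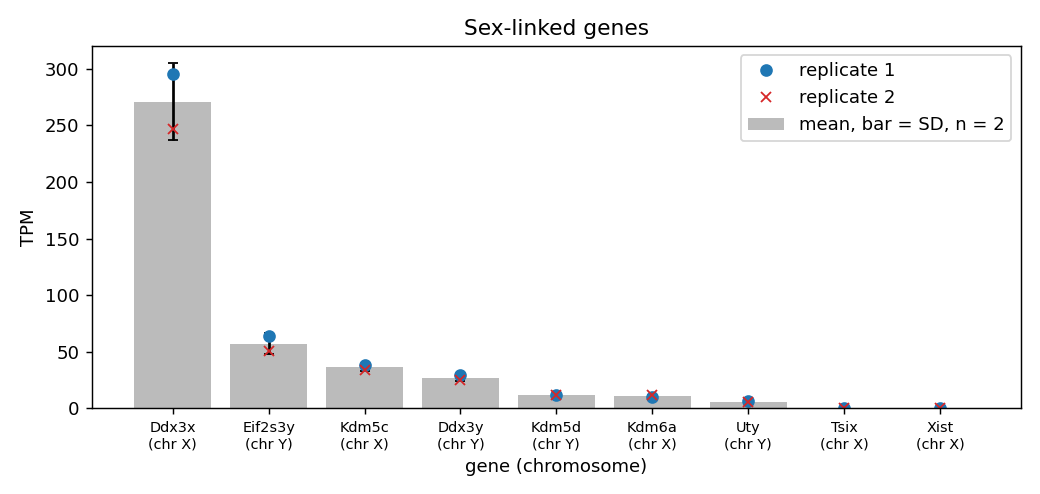
TPM of the sex-linked genes, with bars for the mean, error bars for the SD over n = 2, circles for replicate 1 and crosses for replicate 2. The Y-linked Eif2s3y at 57.1 TPM and Ddx3y at 27.2 TPM stand above Xist, which had 1 and 0 counts.

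Ribosomal protein genes took 5.19% ± 0.268 of the counts and mitochondrial genes 2.53% ± 0.718 (SD, n = 2). Immunoglobulin genes took 0.904% ± 0.0501, MHC genes 0.440% ± 0.0193 and replication-dependent histone genes 0.0333% ± 0.00477. The mitochondrial share was 2.02% in replicate 1 (Wilson 95% interval 2.02% to 2.03%) and 3.04% in replicate 2 (3.03% to 3.05%), a ratio of 1.502. The lincRNA entries Gm42418 and Gm26917, named after their values were seen, are classed here as rRNA-repeat genes. They took 1.10% and 1.60% together, a ratio of 1.45, and the mitochondrial rRNA genes 0.141% and 0.194%, a ratio of 1.38. The 4 pseudogenes Gm10925, Gm28661, Gm29216 and Gm28437, named after their values were seen, share at least 97.2% of their 36-mers with mitochondrial genes and took a further 1.33% and 2.05%. TPM shares were higher for the ribosomal protein (10.98%), mitochondrial (4.65%), immunoglobulin, MHC and histone genes. For Gm42418 and Gm26917 together they were lower than the count shares, at 0.677% and 1.09% in replicates 1 and 2.

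Between the 2 libraries, 4691 of 15340 genes differed in the two-sided exact binomial test after Benjamini-Hochberg adjustment, 2247 higher in replicate 2 and 2444 lower. The share higher was 47.9%, against 51.5% of 4709 calls with DESeq2 size factors and 40.5% of 4680 with library totals. With a log2 ratio of at least 1 in size, 842 genes differed, 236 higher and 606 lower. Most differences were small, and 96.0% of the 10100 genes with a mean of at least 100 counts lay within 0.5 on the log2 scale. Of the 13 mitochondrial protein-coding genes, 11 were higher in replicate 2 and 2 were lower, with a median log2 ratio of 0.57. Of the 13, 2 also passed the negative binomial exact test, mt-Co2, which was higher in replicate 2, and mt-Nd3, which was lower. The mitochondrial genes mt-Co2, mt-Atp6, mt-Co3 and mt-Nd3, named after their values were seen, had a posterior SD over 5% of the count in a library and are uncertain. Each of the 10 genes with the largest ratios of expected counts had a posterior SD over 5% of the count in at least 1 library. Each also had under 1 expected count in 1 library, which can itself raise the posterior SD in percent. In the library with the higher count, the posterior SD was 2.99% for Gm12191, 5.41% for Gm37401 and 6.29% for Gm28911. For the others it lay between 16.07% and 39.85%. Rpl30-ps9, a pseudogene of a ribosomal protein gene on the X chromosome, had 0 and 4751 expected counts in replicates 1 and 2, but 76.96 and 3648 posterior mean counts, a log2 ratio of 5.42. With posterior mean counts the log2 ratio was 4.51 for Gm37401, 3.31 for Rhox4a, 3.26 for Gm10031 and 2.29 for Gm2274, whose expected counts in replicate 1 were under 1. In the other direction, Gm12191 had 4687 and 0.02 expected counts but 4561 and 1068 posterior mean counts, a log2 ratio of -2.23. The log2 ratio with posterior mean counts was -7.83 for Gm28911, -3.95 for Gm13414, -2.90 for Gm28539 and -2.07 for Gm2260, which had 0 expected counts in replicate 2. The size of each of these differences therefore depended on the estimate used, and no fold is given.

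Of 170 genes with a mean of at least 100 counts that passed the test with a log2 ratio of 1 or more in size, 157 (92.4%) had a posterior SD over 5% in a library, against 4.39% of all genes at that mean. A count near 0 in 1 library can itself raise the posterior SD in percent, and by the library with the higher count alone the number was 130 (76.5%) against 3.58%. The coefficient of variation between the replicates was 19.8% over all tested genes and 8.85% over genes with certain read assignment, a filter that can also take out genes near 0 in 1 library. The binomial test holds counting error only, and with the negative binomial exact test 390 genes differed, 104 higher in replicate 2 and 286 lower. Across the 11880 detected genes, which are not independent replicates, log2(TPM + 1) of the libraries had a Pearson r of 0.981 and a Spearman rho of 0.981.

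**Figure D5:**
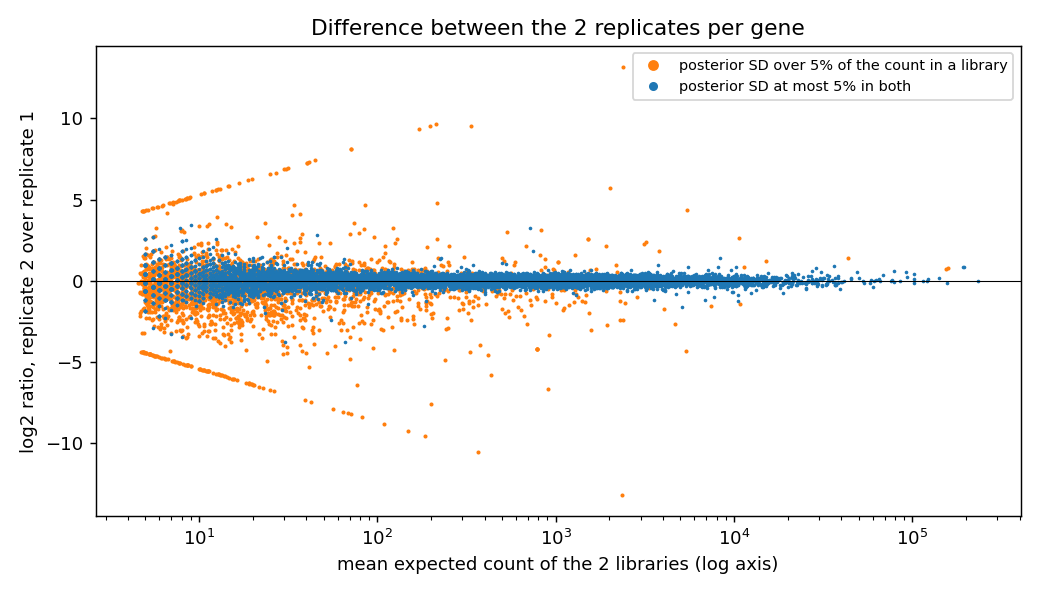
Log2 ratio of replicate 2 over replicate 1 against the mean expected count on a log axis, 1 point per tested gene, orange where the posterior SD exceeds 5% of the count in a library. The 170 large differences at a mean of at least 100 counts include 157 orange points.

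Of the 27 gene lists, 4 had a median log2 ratio between the libraries outside the central 95% of matched random lists, all higher in replicate 2. The B cell identity list had a median of 0.11 at percentile 99.2, with 15 members higher and 3 lower in the exact binomial test and 19 called when adjusted over the list alone. The constant region list had a median of 0.21 at percentile 99.2 with 5 members higher and 0 lower, the same 5 in number as adjusted over the list alone. The reference genes had a median of 0.14 at percentile 99.0 with 9 higher and 3 lower, and the TLR and NF-kB genes 0.11 at percentile 98.2 with 8 higher and 1 lower. Of these lists, 12 reference and 9 TLR and NF-kB genes were called when adjusted over the list alone. No member of any list was called by the negative binomial exact test. Its dispersion was estimated from these same 2 libraries, so it could hardly call small differences and does not speak against the shifts. Of 200 random lists in counts simulated with counting error only, 12 also lay outside the central 95%. The percentiles describe these libraries.

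The median log2 ratios of the other lists lay within the central 95% of matched random lists, where one could be computed. Among them were T cell genes with a median of 0.17 at percentile 91.2, interferon-stimulated genes with -0.16 at percentile 7.7 and myeloid genes with -0.14 at percentile 21. Over members with a mean of at least 100 counts the T cell median was 0.02 at percentile 50.9 and the interferon-stimulated median -0.09 at percentile 15.4. From TPM plus 0.5 the medians were 0.09 at percentile 89.6 for T cell, -0.13 at percentile 16.9 for interferon-stimulated and -0.19 at percentile 15.4 for myeloid genes. Sex-linked genes had a median of 0.09 at percentile 84.4, but -0.19 at percentile 3.7 from TPM plus 0.5. Of the MHC class I genes, 4 were higher and 7 lower in replicate 2 in the exact binomial test, with 13 called when adjusted over the list alone, and of the MHC class II genes 3 and 3, with 7. Glycolysis genes were 3 higher and 6 lower (10 adjusted over the list alone), cholesterol synthesis genes 5 and 4 (12), class switch genes 6 and 5 (12), cell cycle genes 7 and 4 (11), and stress response genes 2 and 5 (8). Isoform genes were 8 higher and 4 lower (12), apoptosis genes and oncogenes 4 and 3 (7), plasma cell genes 2 and 2 (5), sex-linked genes 3 and 1 (4), and germinal centre genes 2 and 1 (3). Interferon-stimulated genes and immediate early and heat shock genes were each 0 higher and 3 lower, with 3 and 1 called when adjusted over the list alone. The B-1 list had 1 higher and 1 lower (2), pro-B and pre-B genes and myeloid genes each 1 and 0 (1), and T cell genes 0 and 2 (1). No hypoxia, NK, erythroid, stromal or epithelial gene was called either way.

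The leading transcript was the same in both replicates for 5585 of 6539 genes at 5 TPM or more with at least 2 annotated transcripts, or 85.4% (Wilson 95% interval 84.5% to 86.2%). That interval treats genes as independent. ENSMUST00000076700.6 held 94.6% ± 1.39 of Ikzf1, Pkm-201 91.9% ± 0.382 of Pkm, Xbp1-201 88.8% ± 2.48 of Xbp1 and Bcl2l1-201 84.8% ± 4.03 of Bcl2l1 (SD, n = 2). Mcl1-201, Cd79a-201 and Fcer2a-201 held 100% each, the latter pair being the 1 annotated transcript. Ptprc-207 held 73.0% ± 13.6, Ikzf3-201 67.9% ± 6.78, Pax5-201 64.9% ± 11.4, Myc-202 58.3% ± 11.3 and Cd44-207 50.7% ± 1.45. Expression was spread widest for Bcl11a-204 at 43.8% ± 1.26, Ezh2-203 at 36.4% ± 10.6 and Tcf3-209 at 30.3% ± 6.17, and Tcf3 had different leading transcripts in the replicates. Short single-end reads give no direct view of whole transcripts, so these shares are estimates.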

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

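The entries that carry only a number as identifier hold signal outside the comparisons of the report. Summed over all of these entries, they held 9798.7 expected counts in replicate 1 and 13851 in replicate 2, and 18255 and 22456 on the TPM scale. The median length of the 26248 entries was 73 nt, and 240 of them had more than 3 counts in both libraries. Read assignment was uncertain for most of the largest entries. The entry with the most counts had 1552.04 and 1.43 expected counts but 321.93 and 221.52 posterior mean counts, with posterior SDs of 261.97 and 226.24. No explanation was tested for this signal, and no biological explanation was tested either.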

How the results depend on the processing

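The posterior mean counts, the limit on read assignment and the removal of mitochondrial and rRNA-repeat genes were chosen after seeing the data. Leaving out 1 of 2 replicates moves a mean by less than its SD by construction, so those settings say nothing about stability. No paired analysis was possible because the labels give 1 group. With a negative binomial exact test at the edgeR common dispersion, 390 genes differed between the libraries in place of 4691, since that test adds the spread estimated from the same 2 libraries. With a log2 ratio of at least 1 required, 842 differed. The coefficient of variation of 19.8% was 16.0% at a mean of 100 counts, 20.004% with no filter beyond 1 count, 17.5% with posterior mean counts and 8.85% for genes with certain read assignment, and the cause of the first 3 moves was not tested. With expected counts and no length scaling, the share of Igkc in Igkc and Iglc2 together was 84.8% in place of 91.8%. As TPM shares in place of count shares, immunoglobulin genes held 2.36%, MHC genes 0.522%, ribosomal protein genes 10.98%, mitochondrial genes 4.65% and histone genes 0.104%, since TPM divides by length. The share of genes with the same leading transcript was 86.4% at 20 TPM or more, outside the interval around 85.4%. The other 44 alternatives of the main results stayed within 1.5 times the count or within 1 SD or interval of the value, among them 9067 to 14162 detected genes and 4 shifted lists in each setting. Of the alternatives for single lists, genes and transcripts, 17 moved and 337 kept their side of the threshold or stayed within range, which does not mean that sizes were kept. The 44 and the 337 both include settings with 1 replicate left out, where mean shares stayed within 1 SD by construction. For those settings the numbers say nothing about stability. With posterior mean counts Gm12191 had a log2 ratio of -2.23 in place of -13.21. From TPM plus 0.5, the median ratio changed sign for 3 lists inside the central range, sex-linked (0.09 to -0.19), pro-B and pre-B (-0.03 to 0.04) and cholesterol synthesis (0.02 to -0.02). Ratios of TPM were not run for single genes as an alternative. Depth limits genes with under 10 counts summed over both libraries, which the reported test left out.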

Other observations

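The tests on Xist counts, on B cell identity genes, on depth, on runs of zeros, on the V to Ighm ratio and on a second V gene were chosen only after the result was seen, and those on runs of zeros and on a second V gene replaced earlier forms that could not decide or were too wide. Some single transcripts stood out. Asns, the asparagine synthetase gene, had 1 and 2 counts, although all of its 36-mers occur in no other gene, while the serine synthesis genes Phgdh and Psat1 stood at 460 ± 84.7 and 308 ± 4.71 TPM (SD, n = 2) and the transcription factor Atf4 at 255 ± 9.07. The lambda constant region Iglc2 stood at 706 TPM while the 3 lambda V genes summed to 12.37 and 11.99 TPM. The mitochondrial tRNA gene mt-Te had 124 and 1317 counts, a log2 ratio of 3.27, and the small nuclear RNA gene Rn7sk 118 and 338 counts. Both were named after their values were seen, among 13 large differences with a posterior SD of at most 5% in both libraries. That limit leaves room for reads moved between near copies. Among the same 13, Rpl39 had 4298 and 12465 counts and the pseudogene Rpl39-ps 14484 and 6689. The lincRNA entry Gm42418, classed here as an rRNA-repeat gene and also named after its values were seen, stood at 4358 and 7852 TPM.

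Y-linked genes were expressed at up to 57.1 TPM and Xist was at or near 0 in a line labelled female. Reads shared with X-linked homologs are argued against, since at least 94.6% of the 36-mers of each of the 4 Y-linked genes occur in no other gene and the posterior SD was at most 0.278% of the count. A minority of male cells among female cells that express Xist is argued against by the highest Xist count of 1. A swap with a culture outside the B lineage is argued against by 23 of 24 B cell identity genes detected. A wrong sex label or a swap with another B cell culture may account for the pattern, and neither was tested.

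Mtap, Cdkn2a and Cdkn2b had 0 counts on chromosome 4, within a run of 9 entries at 0 from 88910557 to 89311039. The nearest entries at 1 TPM or more were Klhl9 below, at 12.5 and 14.0 TPM, and Gm12609 above, at 24.5 and 21.1. Shared sequence is argued against, since at least 99.6% of the 36-mers of each gene occur in no other gene, and so is depth, since 3 counts over both libraries stand for 0.0529 TPM of Mtap. Loss of this stretch from the genome is a candidate explanation, but the zeros inside the run were known beforehand and cannot test it, 316 runs in the genome were as long or longer, and silencing would give the same zeros. An earlier, wider interval, which held 6.79 counts on Gm26525 outside the run, had counted against loss. Loss and silencing cannot be told apart from RNA alone.

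Igha exceeded Ighm by 3.34 ± 0.223 times in TPM (SD, n = 2). Reads of other constant regions are argued against, since 100% of the 36-mers of Igha occur in no other gene and its posterior SD was 0% of the count. Germline transcripts without a V segment as the only source of Igha are argued against by the ratio of Ighv1-53 to Ighm, which was at least 1.97 in both libraries, although 31.7% of its 36-mers were unique and its ratio to Igha plus Ighm was 0.439 and 0.530, against 0.680 and 0.567 for Igkv10-96 to Igkc, so that germline transcripts as part of the Igha signal stay open. A mixture of IgM and IgA cells may still be present, since the second heavy chain V gene held at most 0.686% of heavy chain V TPM, which speaks against separate clones but not against cells of 1 clone of which some switched. That mixture and cells that hold both transcripts cannot be told apart in a bulk library.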
